A study of Mus musculus with 8 samples.

How the data were processed

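Total RNA of mouse tibialis anterior was measured with the Ion AmpliSeq Transcriptome Mouse panel, which amplifies a short segment of each gene, in 4 WT and 4 KO libraries. Groups and replicate numbers were taken from the sample titles. The deposited values were RPM, reads per 1000000 reads, in 1 table of 23930 genes, each named with its amplicon. The submitters' processing notes name the Transcriptome Analysis Console; the aligner, the genome build, the read filters and any use of strand are not given in the sources used here. The labels describe littermate mice but do not state that each library came from a separate animal, so p-values measure the spread between these libraries.

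Every value in each column was a whole multiple of what 1 read was worth in that library (100% of values within a tolerance of 0.05 reads), which gave totals of 7091352, 5989770, 7014063 and 6175348 reads for WT 1 to 4 and 6086665, 4774602, 5603278 and 7281574 for KO 1 to 4. Amplicon reads carry no molecular identifiers, so intervals and floors cover counting error only, and the floor was set at 3 reads. No pair of replicates agreed within sampling noise (chi-square per degree of freedom at least 8.73), and all 8 libraries were counted separately. That check compares pairs with counting error only and cannot show that they came from separate animals. An amplicon panel measures 1 segment per gene and cannot separate isoforms, and scaling to a fixed total lets abundant muscle transcripts set the level of the rest: the 50 most abundant genes took 29.3% to 41.6% of reads.

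Genes with at least 1 RPM in at least 4 libraries (11087) were tested on log2(RPM + 1) with limma 3.58.1 in R 4.3.3 (linear model on genotype, empirical Bayes with a variance trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). A fold change on this scale understates the change of low genes. The targeted gene was tested by an exact two-sided permutation of mean RPM over 70 assignments. The 45 gene lists fixed before the data were examined were tested with camera (limma), which compares a list with all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 41 lists with at least 5 tested members; the estimated correlation was used beside it. Lists overlap in part and hold 848 genes, of which 764 were in the table and 685 were tested; the others are not analysed here. For each list, p-values were also adjusted over the list alone.

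The genes named were chosen by a rule fixed before the data were examined: the succinate dehydrogenase list; the 10 rising and 10 falling genes with the largest change among those that passed and whose groups did not overlap; and, from each list, up to 4 members with the smallest p together with members given as examples that did not pass. Gene locations came from GENCODE M21 on GRCm38 by gene symbol, which matched 150 of the 152 genes in the table of named genes. Of these, 57 overlap a gene on the other strand and 20 a gene on the same strand, so that reads could be shared.

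Alternatives planned before the data were examined were pseudocounts of 0.5 and 5, no filter and a filter of 5 RPM, TMM factors, quantile normalization, no variance trend, array weights, the replicate number as a block, omission of each library, rank-based camera, and, on the recovered reads, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0. Those added after the data were seen were a term for the libraries with Xist above 10 RPM, the 6 libraries below that level alone, omission of WT 3 and KO 3, whose TMM factors of 0.898 and 1.139 lay farthest apart, and edgeR without TMM. Other splits of the 8 libraries into 4 and 4 (35 in all) were refitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

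The steps were tested on simulated data made from the real means and read totals of the KO and WT libraries (10968 genes). At 1.5-fold, 2-fold and 4-fold changes limma recovered 20.9%, 82.1% and 98.5% of the changed genes and edgeR 22.4%, 85.1% and 98.5%. The changed genes were drawn from those with a mean of at least 5 RPM, so these shares do not cover lower genes. Of the calls, 10.1% in limma and 9.27% in edgeR were unchanged genes, and the limma share averaged 6.13% over 20 draws. Camera called 5 of 5 changed and 0 of 40 unchanged lists, and all 8 read totals were recovered exactly. Every member of a changed list was raised by the same log2 amount, so these lists were easy to call. That amount was above the median shift of the endothelial list relative to all genes (0.3). The simulated genes were drawn independently and the lists were random sets of them. The simulation therefore cannot show how often camera calls unchanged lists whose genes move together. In the real data the estimated correlation was 0.64 in the tendon list and 0.29 in the endothelial list. It was 0 for hypoxia-inducible factor targets and 0.01 for excitation-contraction coupling, at or near the preset 0.01. Both of these lists also lost their calls with an estimated correlation (camera adjusted p = 0.12). A call lost in that setting therefore does not by itself show that the genes of a list move together.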

Results

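RNA from the tibialis anterior, a fast muscle of the mouse lower leg, was profiled by targeted sequencing of 1 amplicon per gene in 8 libraries. Of these, 4 came from mice in which Sdhc was deleted in skeletal muscle by a tamoxifen-induced Cre recombinase (KO) and 4 from induced littermates that carried the recombinase but no floxed allele (WT). Induction took place at 12 weeks of age and muscle was taken 20 weeks later. Library totals were 7.09, 5.99, 7.01 and 6.18 M reads (M, 1000000) for WT 1 to WT 4 and 6.09, 4.77, 5.6 and 7.28 M reads for KO 1 to KO 4. The mean total was 5.94 M reads in KO and 6.57 M reads in WT (exact two-sided permutation p = 0.343, n = 4 per group), and 3 reads corresponded to between 0.412 and 0.628 RPM (reads per 1000000 reads). Xist, the transcript of the inactive X chromosome, stood at 77.3 RPM in WT 1 and 98.9 RPM in KO 4, where the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at 0. In the other 6 libraries Xist was at most 0.334 RPM and Ddx3y lay between 78.6 and 91.5 RPM. The labels used here do not give the sex of the animals.

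The first comparison asked whether the targeted transcript was lost, which checks the labels. Sdhc, which encodes a membrane anchor subunit of succinate dehydrogenase (respiratory complex II), fell from 696 ± 91.8 RPM in WT to 26 ± 16 RPM in KO (mean ± SD, n = 4 each). The KO level was 3.73% ± 2.3 of the WT mean, a drop of 96.3% (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). The WT libraries held 574, 693, 795 and 722 RPM. The KO libraries held 17.1, 14.5, 22.8 and 49.4 RPM, from 69 to 360 reads per library, and the highest of these, KO 4, had an exact 95% binomial interval (Clopper-Pearson) of 44.5 to 54.8 RPM that covers counting error only. Each omission of 1 library left the KO level below the WT level, with an exact permutation p of 0.0571, the smallest that 3 against 4 can give. The gene (ENSMUSG00000058076.12, protein coding) spans chromosome 1 from 171127165 to 171150603 on the minus strand of GRCm38. The position of its amplicon (AMPLSdhc_3_1.7242) relative to the deleted part is not given in the sources used here, so the value measures transcripts that hold the amplicon and not the share of recombined alleles.

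**Figure D1:**
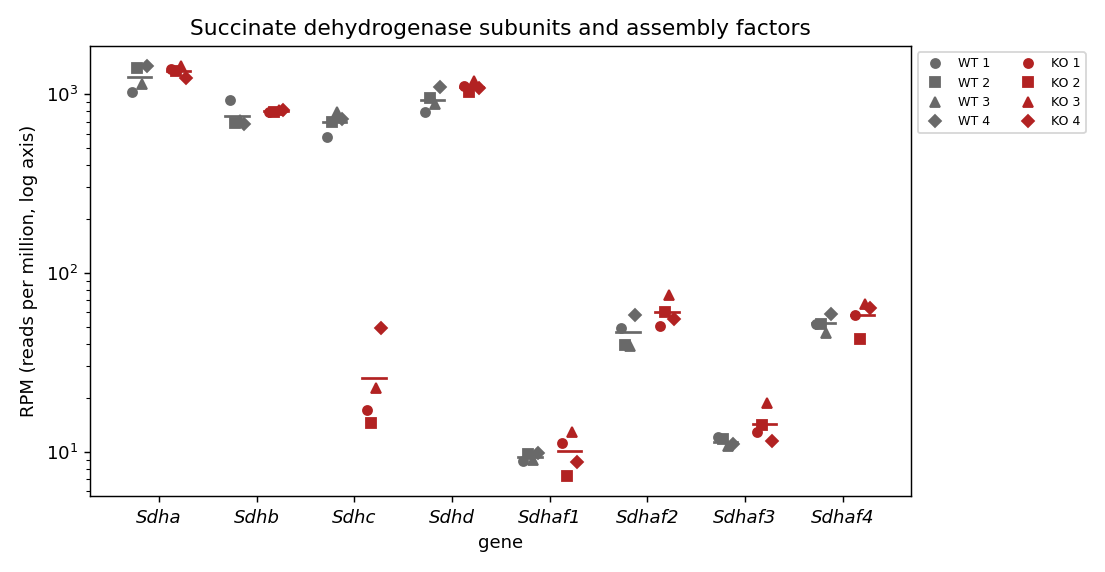
RPM on a log axis for the 4 subunits of succinate dehydrogenase and its 4 assembly factors, with 1 point per library (grey, WT; red, KO; n = 4 each) and a horizontal line at each group mean. The KO libraries of Sdhc lie between 14.5 and 49.4 RPM and the WT libraries between 574 and 795 RPM.

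None of the other 7 members of the complex II list passed the test in limma, where Sdhaf2 alone had an unadjusted p under 0.05 and edgeR called none of them. Sdha, the flavoprotein subunit, stood at 1341.5 ± 85.4 RPM in KO and 1244 ± 194 RPM in WT (limma adjusted p = 0.692, n = 4 each). The iron-sulphur subunit Sdhb stood at 798 ± 12.1 against 752 ± 120 RPM (adjusted p = 0.739), and the second anchor subunit Sdhd at 1097 ± 64.9 against 928.5 ± 130 RPM (adjusted p = 0.354). The assembly factors Sdhaf1 to Sdhaf4 had adjusted p of 0.89, 0.278, 0.419 and 0.704. Log2 fold changes of the 7 lay between 0.07 and 0.37 on the deposited scale, and those of Sdha, Sdhb and Sdhaf1 turned negative, at -0.01, -0.03 and -0.05, once the libraries were rescaled by TMM factors (trimmed mean of M values). The list as a whole did not differ from other genes (camera adjusted p = 0.521). That test includes Sdhc itself, so it does not single out the other 7 members.

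Across all 11087 genes tested, 89 differed between KO and WT in limma at an adjusted p under 0.05, 58 higher and 31 lower in KO. In 88 of them all 4 KO libraries lay on one side of all 4 WT libraries; the exception, named after its values were seen, was 1700001O22Rik, which fell from 15.2 ± 8.75 to 1.54 ± 1.11 RPM. At an unadjusted p under 0.05 there were 1790 of the 11087 genes, the background for such counts in the lists. Among all genes tested, 9.1% showed no overlap between the groups, against 2.86% by chance. On the deposited scale the excess lay on the higher side: 831 genes (7.5%) were higher in all 4 KO libraries and 178 (1.61%) lower, against 1.43% by chance on each side. With TMM factors, a count added after the result was seen, 394 (3.55%) were higher and 412 (3.72%) lower. The median gene was 0.13 higher in KO on the log2 scale of the deposited values. Log2 fold changes below are given relative to that median unless stated otherwise. Their SE and limma p-values come from the fit on the deposited scale and do not test the distance from the median. The printed value of a rising gene is therefore smaller than the difference tested, and that of a falling gene is larger. Differences in the mean log2 values of a list, and counts of positive log2 fold changes, are on the deposited scale. That median fell to 0.08 without KO 3 and to 0.06 without WT 3 and KO 3. It lay between 0.1 and 0.15 when another single library was left out. Rescaling by TMM factors moved the median to 0.006 and gave 39 higher and 65 lower genes, of which 70 were among the 89; 19 of the higher calls and 0 of the lower calls were lost. The edgeR quasi-likelihood test on the recovered reads called 92 genes, 37 higher and 55 lower, with 68 shared, and DESeq2 called 240, 83 higher and 157 lower, with 85 shared. The count depended on single libraries. It was 158, 26, 16 and 56 without WT 1 to WT 4 and 29, 50, 30 and 263 without KO 1 to KO 4. In fits chosen after the data were seen, a term for the libraries with Xist gave 235 genes that held all 89, the 6 libraries without Xist gave 392 with 83 shared, and leaving out WT 3 and KO 3 gave 9. Of the 63 named genes outside the 89, 15 passed with the Xist term: Kdm3a, Stc2, Camk2a, Cox8b, Cox7a2, Eci1, Tnnc1, Sparc, Col4a1, Pygm, Cdkn1a, Hspa1b, Egr1, Xirp1 and Actc1. Sdhc, Egln3, Mthfd2, Ankrd1, Gadd45a, Car9, Car1, Gm20735 and Slc38a4, 9 genes in all, passed in every alternative in which they were tested.

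On the log2(RPM + 1) scale, the largest increases were in Ankrd1, Egln3 and Mthfd2. Ankrd1, a titin-binding ankyrin repeat protein induced by mechanical and other stress in muscle, rose from 18 ± 8.19 to 95.5 ± 27.6 RPM (relative log2 fold change 2.27, SE 0.27, limma adjusted p = 3.56e-04). Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factor (HIF) and is itself induced by it, rose from 15.3 ± 5.68 to 79.2 ± 5.76 RPM (2.24, SE 0.21, adjusted p = 2.9e-05). Mthfd2, a mitochondrial enzyme of folate-dependent one-carbon metabolism, rose from 10.6 ± 1.75 to 55.4 ± 20.9 RPM (2.09, SE 0.23, adjusted p = 1.33e-04). The genes lie on GRCm38 chromosome 19 from 36111961 to 36120099, chromosome 12 from 54178981 to 54203860 and chromosome 6 from 83305691 to 83325908. Next came Car9, a cell-surface carbonic anhydrase (1.77), the secreted peptide apelin, Apln (1.58), the long non-coding RNA Gm20735 (1.49) and the secreted metalloproteinase Adamts20 (1.47). WT means of Apln, Gm20735 and Adamts20 were 1.3, 1.01 and 1.05 RPM. Apln was at the floor of 3 reads in WT 3 (0.428 RPM), and Gm20735 was below it in WT 2 (0.334 RPM). Gadd45a, a growth arrest gene that denervated muscle induces, rose from 60.9 ± 17.8 to 182 ± 32.2 RPM (1.46, adjusted p = 3.56e-04). Trib3, a pseudokinase of the integrated stress response (1.43), and Srrm4os (1.37) completed the 10. Srrm4os is antisense to Srrm4, and whether the counting used strand is not given in the sources used here. The calls of Trib3 and Srrm4os were lost in 9 of 22 and 8 of 21 alternatives. Trib3 was at the floor of 3 reads in WT 4 (0.486 RPM), and Srrm4os was at it in WT 3 (0.428 RPM). The groups of Trib3 were barely apart, at 2.2 RPM in KO 4 and 2.17 RPM in WT 2. The added 1 RPM shrinks changes of low genes, and edgeR on recovered reads ordered them otherwise. There Irx5, named after its values were seen, came to 2.52 (0.318 ± 0.203 RPM in WT, 2.02 ± 0.468 in KO, edgeR adjusted p = 0.0143). Srrm4os came to 2.29, against 2.26, 2.24 and 2.23 for Ankrd1, Mthfd2 and Egln3. Irx5 was at or below the floor of 3 reads in WT 1 to WT 4 (0.141, 0.501, 0.143 and 0.486 RPM), so the size of its change is poorly measured.

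After Sdhc, the largest decrease without overlap was in Mettl21c, a protein lysine methyltransferase of muscle, which fell from 94.2 ± 48 to 19.8 ± 5.9 RPM (relative log2 fold change -2.14, SE 0.38, limma adjusted p = 0.0192, n = 4 each). Mettl21c was lower in the libraries with Xist in both groups, at 25.8 RPM in WT 1 against 97.4 to 133 RPM in the other WT libraries and at 12.1 RPM in KO 4 against 18.2 to 24.7 RPM in the other KO libraries. Slc38a4, an amino acid transporter, fell from 92.8 ± 23 to 29.5 ± 8.44 RPM (-1.75, SE 0.22, adjusted p = 0.00182). Tmem37 (-1.71), Lrtm2 (-1.54), Tceal5 (-1.48), the secretin receptor Sctr (-1.46), the kinase Nek6 (-1.36), the potassium channel subunit Kcng4 (-1.36) and the arsenite methyltransferase As3mt (-1.32) followed. Adjusted p of these 7 genes lay between 0.00946 and 0.0421. Of the 9 genes, Slc38a4 kept its call in all 23 alternatives and As3mt lost it in 1, whereas Kcng4 lost it in 10.

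**Figure D2:**
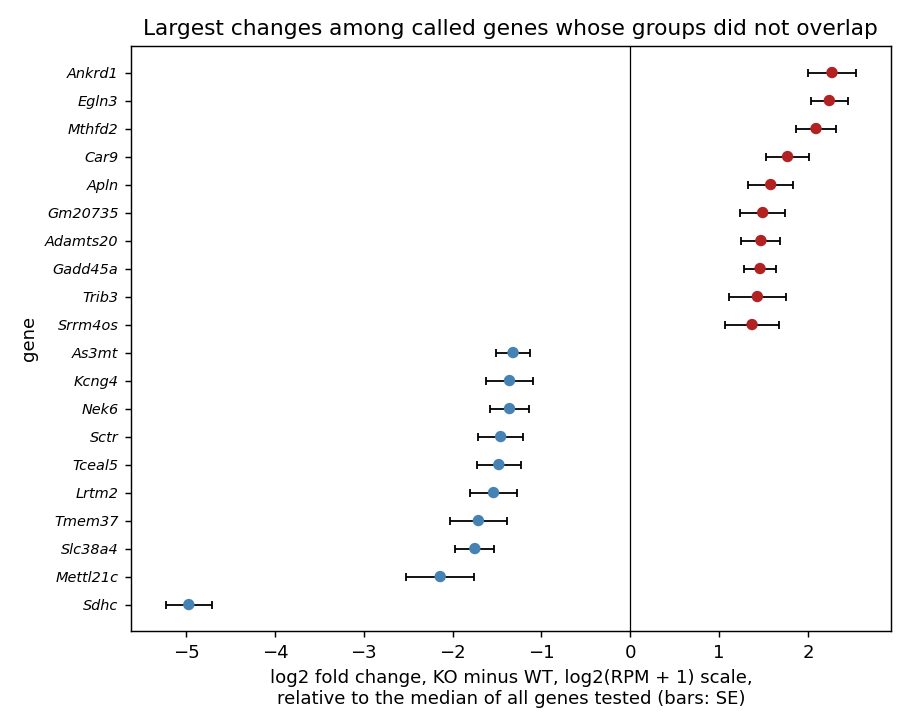
Log2 fold change (KO minus WT on the log2(RPM + 1) scale, relative to the median of all genes tested) of the 10 rising and 10 falling genes with the largest changes among those that passed the test with no overlap between the groups; bars are standard errors, n = 4 libraries per group. Sdhc lies at -4.97 and the other 19 between -2.14 and 2.27.

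Genes that HIF induces lay higher in KO than other genes did (25 tested members, camera adjusted p = 0.00101; adjusted p = 0.124 with an estimated correlation). Of these, 3 rose (Egln3, Car9 and P4ha1) and 0 fell in limma (1 was lower at an unadjusted p under 0.05, none by edgeR), while 11 rose and 1 fell when adjusted over the list alone. P4ha1, a subunit of collagen prolyl 4-hydroxylase, rose from 30.5 ± 4.38 to 61.5 ± 16.6 RPM (relative log2 fold change 0.84, adjusted p = 0.0165). The histone demethylase Kdm3a (0.6, adjusted p = 0.0799), hexokinase 2, Hk2 (0.37, adjusted p = 0.112), and the angiogenic factor Vegfa (0.23, adjusted p = 0.169) did not pass. The list's median lay 0.2 above that of all genes. A term for Xist gave 4 rising members, as did the 6 libraries without Xist. Egln3 and P4ha1 also belong to the list of succinate and 2-oxoglutarate dependent enzymes and receptors, whose 20 tested members did not differ from other genes as a group (2 rose, 0 fell; camera adjusted p = 0.323). Markers of endothelial cells lay higher in the same KO libraries (median 0.3 above all genes; camera adjusted p = 2.9e-04; adjusted p = 0.452 with an estimated correlation).

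Genes of the mitochondrial integrated stress response lay higher as a group (27 tested members, camera adjusted p = 0.00902; adjusted p = 0.338 with an estimated correlation). Mthfd2 and Trib3 rose, 0 members fell in limma (1 with an unadjusted p under 0.05, none by edgeR), and 10 rose and 1 fell when adjusted over the list alone. Stc2 (relative log2 fold change 0.85, adjusted p = 0.0505), Pycr1, an enzyme of proline synthesis (0.8, adjusted p = 0.0799), and Ddit3, which encodes the transcription factor CHOP (0.6, adjusted p = 0.127), did not pass. Stc2 was below the floor of 3 reads in WT 2 to WT 4 (0.334, 0.285 and 0.324 RPM). Atf4, whose product drives this response, stood at 311 ± 33.7 RPM in KO and 336 ± 40 in WT (adjusted p = 0.711). The hormone genes Fgf21 and Gdf15 were too low to test: Fgf21 had no read in 7 libraries, which allows up to 0.628 RPM in KO 2, and Gdf15 was at most 0.657 RPM, in KO 1. The call of the list ended without WT 4 (adjusted p = 0.071), without KO 1 (0.0686), without KO 2 (0.0702) and with a minimum of 5 RPM (0.327).

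**Figure D3:**
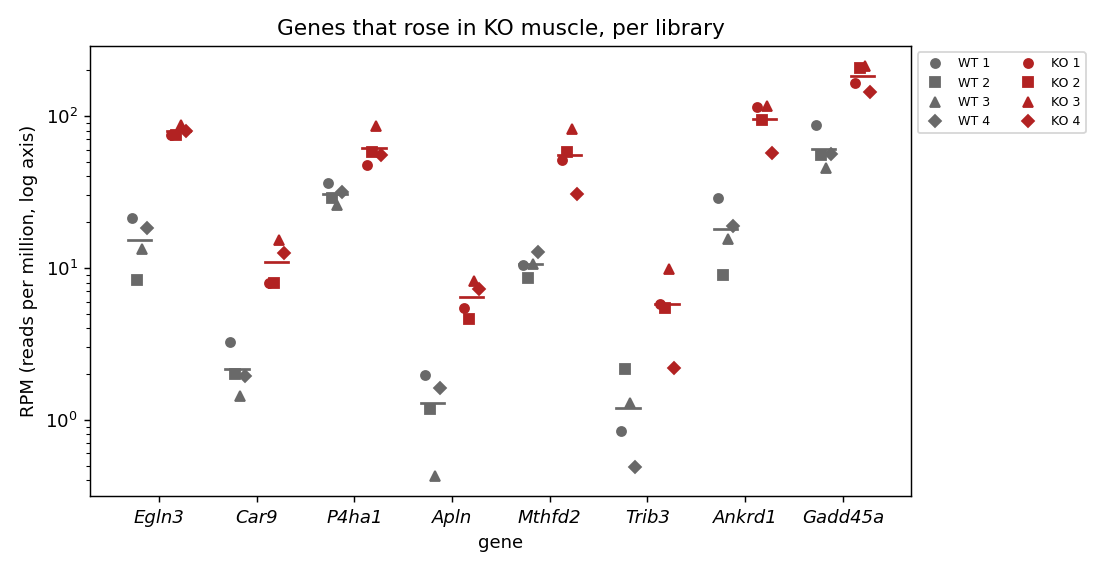
RPM on a log axis for 8 genes that rose in KO, with 1 point per library (grey, WT; red, KO; n = 4 each) and a line at each group mean. All 4 KO libraries lie above all 4 WT libraries for each gene, and KO 4 has the lowest KO value of Mthfd2, Trib3, Ankrd1 and Gadd45a.

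Fast fibre contractile genes lay lower in KO (16 tested members, 0 with a positive log2 fold change, median 0.35 below that of all genes; camera adjusted p = 1.07e-07; adjusted p = 0.338 with an estimated correlation). The mean log2 values of the list overlapped between the groups (difference -0.26, exact permutation p = 0.0857, n = 4 each), with WT 4 (12.02) below KO 1 (12.13) and KO 2 (12.11). Endothelial markers rose in the same KO libraries (difference 0.42, unadjusted exact permutation p = 0.0286, camera adjusted p = 0.452 with an estimated correlation). That exact p is the smallest possible. The lists of HIF targets, stress response, complex IV and fatty acid genes reached it too. So did those of complex II, complex V, mitochondrial biogenesis regulators and 2-oxoglutarate dependent enzymes, which camera did not call. Mylk2, the myosin light chain kinase of skeletal muscle, fell from 2910.2 ± 394 to 1731 ± 116 RPM (relative log2 fold change -0.87, SE 0.13, limma adjusted p = 0.0165) and was the only member to pass in limma, a call lost in 6 of 23 alternatives. The Z-disc gene Myoz1 (-0.62, limma adjusted p = 0.087) also fell when adjusted over the list alone, and it passed with Mylk2 with TMM factors (adjusted p = 0.0383) and in edgeR (0.0408). The fast myosin heavy chains Myh1 (-0.48, adjusted p = 0.34) and Myh4 (-0.46, adjusted p = 0.487) and troponin Tnnt3 (-0.4, adjusted p = 0.52) did not pass, and after quantile normalization Myh1 stood at 0.04 and Tnnt3 at 0 on the deposited scale and the list's call ended (adjusted p = 0.0576). Slow and oxidative fibre genes did not differ as a group (13 tested, camera adjusted p = 0.889). None of them passed in limma or edgeR, 4 had an unadjusted p under 0.05, and 3 rose when adjusted over the list alone, Tnnc1 (0.94), Atp2a2 (0.43) and Tnni1 (0.65).

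Genes of excitation-contraction coupling and calcium handling also lay lower (25 tested members, median 0.24 below that of all genes; camera adjusted p = 2.29e-04; adjusted p = 0.124 with an estimated correlation). The mean log2 values overlapped (difference -0.1, exact permutation p = 0.0857, n = 4 each), with WT 1 (7.99) below KO 3 (8.02) and KO 4 (8.06). As above, endothelial markers rose in the same KO libraries (difference 0.42, unadjusted exact permutation p = 0.0286, camera adjusted p = 0.452 with an estimated correlation). No member passed in limma or in edgeR; 1 was higher and 5 were lower at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. That gene was Camk2a, a calcium-dependent kinase, at a mean of 369 RPM in KO and 569 RPM in WT (relative log2 fold change -0.78, SE 0.17, adjusted p = 0.0799). Mrln, which encodes the calcium pump inhibitor myoregulin (-0.74, adjusted p = 0.141), and the ryanodine receptor Ryr1 (-0.38, adjusted p = 0.392) did not pass.

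Among the respiratory complexes, complex IV genes lay higher (13 tested members, 12 with a positive log2 fold change on the deposited scale, median 0.18 above that of all genes; camera adjusted p = 0.0129; adjusted p = 0.343 with an estimated correlation). No member passed in limma or edgeR and 5 were higher at an unadjusted p under 0.05; adjusted over the list alone 3 rose, Cox8b (0.42), Cox7a2 (0.41) and Cox6a1 (0.23). The list's call ended with TMM factors (adjusted p = 0.0639), without WT 2 (0.104) and without KO 1 (0.0862). The lists of complex I (31 tested, camera adjusted p = 0.114), complex III (9 tested, 0.323) and complex V (10 tested, 0.643) did not differ from other genes. They held no gene that passed in limma or edgeR. At an unadjusted p under 0.05 they held 5, 2 and 1 genes, all higher, where 1790 of all 11087 genes tested reached that level. Uqcrb of complex III rose when adjusted over its list alone. The tricarboxylic acid cycle list did not differ either (20 tested, camera adjusted p = 0.643). Its 1 called member was Me2, the mitochondrial malic enzyme, which rose from 3.48 ± 0.644 to 7.36 ± 0.733 RPM (relative log2 fold change 0.78, adjusted p = 0.0252) and was lost in edgeR (adjusted p = 0.0535). Citrate synthase, Cs (1197 ± 142 RPM in KO, 1121 ± 72.2 in WT, adjusted p = 0.764), stood at 0.09 on the deposited scale and at -0.04 with TMM factors. Fumarase, Fh1, did not pass (adjusted p = 0.388).

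The lists of mitochondrial ribosome and translation (33 tested, camera adjusted p = 0.349), mitochondrial biogenesis regulators (17 tested, 0.416), mitochondrial chaperones and proteases (14 tested, 0.643), and fusion, fission and mitophagy (20 tested, 0.824) did not differ from other genes. They held 0 genes that passed in limma. At an unadjusted p under 0.05 they held 8, 3, 3 and 4 genes, and edgeR called 1, in the last list. Ppargc1a, the coactivator of mitochondrial biogenesis, stood at 184.5 ± 35.7 RPM in KO and 152 ± 39.1 in WT (adjusted p = 0.43), and the mitophagy receptor Bnip3 at 75.4 ± 7.35 and 55.9 ± 12 RPM (adjusted p = 0.194).

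Fuel genes moved in part. The fatty acid uptake and oxidation list lay higher (28 tested members, median 0.09 above that of all genes; camera adjusted p = 0.0328; adjusted p = 0.78 with an estimated correlation). The fatty acid binding protein Fabp4 (194 ± 31.2 to 302 ± 31.5 RPM) and the acyl-CoA synthetase Acsl1 (199.8 ± 34.9 to 309 ± 23.4 RPM) rose, with adjusted p of 0.0404 and 0.0442, and 5 members rose when adjusted over the list alone. Both genes lost their calls with TMM factors (adjusted p = 0.073 and 0.0711), as did the list (0.07); the list's call also ended without WT 2 (0.12), WT 3 (0.0725), KO 1 (0.121) or KO 4 (0.173), with a minimum of 5 RPM (0.0663) and without a variance trend (0.131). In all, the list lost its call in 8 of 22 alternatives, and Fabp4 and Acsl1 lost theirs in 10 and 14 of 23. Fabp4 is also an adipocyte and capillary marker, and the adipocyte list did not differ (5 tested, 1 rose; camera adjusted p = 0.747), whereas endothelial markers lay higher (12 tested, median 0.3 above that of all genes; camera adjusted p = 2.9e-04; adjusted p = 0.452 with an estimated correlation). In the glycolysis and glycogen list (27 tested, camera adjusted p = 0.691), Gbe1, the glycogen branching enzyme, rose from 135 ± 22.6 to 225 ± 24.6 RPM (relative log2 fold change 0.62, adjusted p = 0.0192). Glycogen phosphorylase, Pygm, stood at 9358 ± 1525 RPM in KO and 14636 ± 2575 in WT (-0.77, adjusted p = 0.077), and lactate dehydrogenase Ldha at 4063 ± 248 and 3258 ± 446 RPM (adjusted p = 0.26). In lipid and cholesterol synthesis (21 tested, camera adjusted p = 0.138) the lipogenic regulator Thrsp rose from 11.8 ± 4.2 to 26.6 ± 5.94 RPM (adjusted p = 0.0192). The phosphagen and adenine nucleotide list held no called gene in limma, 1 in edgeR and 2 at an unadjusted p under 0.05 (17 tested, camera adjusted p = 0.133).

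Genes of muscle wasting did not move as a group (25 tested members, camera adjusted p = 0.85). The ubiquitin ligase genes Fbxo32 (747 ± 280 RPM in KO, 741 ± 102.2 in WT, adjusted p = 0.928) and Trim63 (574 ± 86.9 and 662 ± 49.7 RPM, adjusted p = 0.434) did not pass. On the deposited scale, the sign of Fbxo32 changed without WT 4, KO 1 or KO 4. Mstn, which encodes the growth inhibitor myostatin, fell from 60.9 ± 6.42 to 37.5 ± 3.35 RPM (relative log2 fold change -0.81, SE 0.14, adjusted p = 0.0251). In the growth signalling list (23 tested, camera adjusted p = 0.955) the kinase Akt1 rose from 125 ± 14.9 to 205 ± 17.7 RPM (0.59, adjusted p = 0.0165) and Smad3, a transducer of myostatin and TGF-beta signals, fell from 53.2 ± 8.78 to 30.4 ± 7.55 RPM (-0.93, adjusted p = 0.0442). The lists of developmental and regenerating fibre genes (18 tested, camera adjusted p = 0.0894) and of denervation and neuromuscular junction genes (20 tested, 0.349) held 1 called gene each, Ankrd1 and Gadd45a. Xirp1 (0.48, adjusted p = 0.0651) and Actc1 (0.6, adjusted p = 0.101) of the first did not pass. Both passed with the Xist term (adjusted p = 0.0291 and 0.0144). That list had 4 rising members with the term and 5 in the 6 libraries without Xist. In the p53 and senescence list (14 tested, camera adjusted p = 0.698) Phlda3 rose from 101.9 ± 6.79 to 177 ± 33.7 RPM (adjusted p = 0.0184), and Cdkn1a did not pass (adjusted p = 0.128). Cdkn1a stood at 60.8 RPM in WT 1, a library with Xist, and passed with the Xist term (adjusted p = 0.00229). Its list had 2 rising members and 1 falling member with that term, and 1 falling member with TMM factors and in edgeR. In the list of angiogenic factors and myokines (16 tested, camera adjusted p = 0.245), Apln and the nicotinamide riboside kinase Nmrk2 (0.69, adjusted p = 0.0158) rose and Mstn fell. The calls of Mstn, Akt1, Smad3, Phlda3 and Nmrk2 were lost in 8, 5, 11, 6 and 3 of 23 alternatives. Their largest adjusted p in these alternatives were 0.0934, 0.202, 0.208, 0.231 and 0.211, in that order.

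Markers of endothelial cells lay higher in KO (12 tested members, all 12 with a positive log2 fold change on the deposited scale). The camera adjusted p was 2.9e-04, and 0.452 with an estimated correlation. No single member passed in limma or edgeR, 8 were higher at an unadjusted p under 0.05, and 7 rose when adjusted over the list alone. VE-cadherin, Cdh5, stood at 103.2 ± 19 RPM in KO and 68.3 ± 13.4 in WT (relative log2 fold change 0.47, adjusted p = 0.101), and Pecam1 at 239 ± 18.3 and 167 ± 41.8 RPM (0.42, adjusted p = 0.118). Tendon markers lay lower (8 tested, median 0.53 below that of all genes; camera adjusted p = 7e-05; adjusted p = 0.452 with an estimated correlation). Their mean log2 values overlapped between the groups, at 4.18, 4.33, 3.79 and 3.61 in WT 1 to WT 4 and 3.18, 2.95, 3.75 and 4.21 in KO 1 to KO 4 (difference -0.46, exact permutation p = 0.229, n = 4 each), with KO 4 above 3 of the 4 WT libraries. Scx, the transcription factor of tendon cells, fell from 19.7 ± 2.56 to 8.77 ± 2.55 RPM (-1.24, adjusted p = 0.0164), and Thbs4, Fmod and Tnmd did not pass (adjusted p = 0.373, 0.411 and 0.453). Among macrophage markers (9 tested, camera adjusted p = 0.192) Cd68 rose from 3.92 ± 0.865 to 9.95 ± 2.97 RPM (1.01, adjusted p = 0.0192). The markers of fibroblasts (11 tested, camera adjusted p = 0.643), smooth muscle and pericytes (9 tested, 0.643), satellite cells (11 tested, 0.707) and Schwann cells (5 tested, 0.349) did not differ from other genes and held no called gene in limma or edgeR, with 3, 3, 2 and 0 genes at an unadjusted p under 0.05. Erythroid, neutrophil, lymphocyte and sex-linked lists had fewer than 5 genes above the filter and were not tested as groups.

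Interferon-stimulated genes lay higher (20 tested members, 19 with a positive log2 fold change on the deposited scale, median 0.24 above that of all genes; camera adjusted p = 0.00765; adjusted p = 0.741 with an estimated correlation). The mean log2 values overlapped (difference 0.41, exact permutation p = 0.0857, n = 4 each), with KO 2 (3.31) below WT 4 (3.37). Endothelial markers rose in the same KO libraries (difference 0.42, unadjusted exact permutation p = 0.0286, camera adjusted p = 0.452 with an estimated correlation). No member passed in limma or edgeR, 9 were higher at an unadjusted p under 0.05, and 3 rose when adjusted over the list alone, Irf7 (0.77), Gbp3 (0.69) and Oasl2 (0.68). The list's call ended without KO 1 (adjusted p = 0.066) and with a minimum of 5 RPM (0.0663). The lists of inflammation and complement (11 tested, camera adjusted p = 0.85), extracellular matrix (26 tested, 0.349), antioxidant and NRF2 targets (25 tested, 0.349) and iron and heme (17 tested, 0.349) did not differ from other genes. They held no called gene in limma, and 0, 7, 5 and 5 genes at an unadjusted p under 0.05; edgeR called 1, in the iron list. Sparc (0.51, adjusted p = 0.0651) and Col4a1 (0.56, adjusted p = 0.0799) rose when adjusted over the matrix list alone. Hmox1 and Nqo1, both targets of NRF2, did not pass (adjusted p = 0.169 and 0.343). Genes that respond to handling, the immediate early and heat shock list (14 tested, camera adjusted p = 0.349) and the circadian clock list (15 tested, 0.445), did not differ as groups and held no called gene in limma or edgeR, with 4 and 1 genes at an unadjusted p under 0.05. Egr1 stood at 57 ± 47.7 RPM in KO and 14.9 ± 9.49 in WT (adjusted p = 0.0575).

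In all, 9 of the 41 lists tested differed from other genes, 6 higher and 3 lower in KO, and none did with an estimated correlation, where the smallest adjusted p was 0.124. With TMM factors 7 did, and without KO 1 the number was 5. In 12 lists the median or mean log2 fold change on the deposited scale differed in sign from the test, none of them among the 9.

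**Figure D4:**
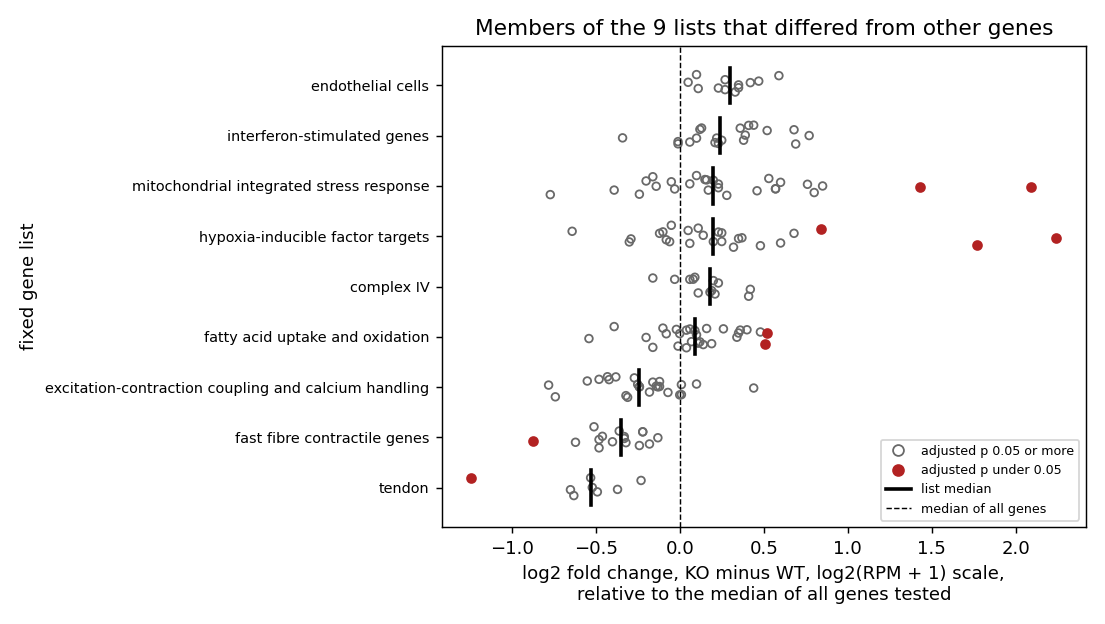
Log2 fold change (KO minus WT on the log2(RPM + 1) scale, relative to the median of all genes tested) of the tested members of the 9 lists that differed from other genes; filled points passed the limma test over all genes and vertical bars mark list medians. List medians lie between -0.53 for tendon and 0.3 for endothelial cells, and most members of each list did not pass on their own.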

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

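The tests of the share of reads on abundant genes, of both explanations for the endothelial markers and of non-fibre RNA in KO 4 were chosen after the result was seen, and the bound of the last was changed once its value was known; the splits of the samples, the test of depth and the test of an additive effect of sex were written before. Of 304 groups of 4 libraries examined among the 152 genes in the table of named genes, which holds all 89 that differed, 21 held 1 library far from the other 3, where chance would give 15.2. Those not named elsewhere are named here for this after their values were seen. In WT 1 these were Sdhb (929.6 RPM, the others up to 716), Slc38a4 (58.5, the nearest other 100.9), 1700001O22Rik (2.12, the nearest other 18.9), Stc2 (0.987, the nearest other 0.334), Cdkn1a (60.8, the nearest other 23.5) and Xirp1 (75.4, the nearest other 58). They were Gm7854 (6.51 RPM, the nearest other 4.21) and Mpp3 (37.2, the nearest other 25.2) in WT 2, and Ddit3 (40, the nearest other 30.7) and Exoc7 (29.1, the nearest other 39.8) in WT 4. In KO 1 they were Egr1 (128 RPM, the nearest other 41.4), Mrln (95.1, the nearest other 165.1) and Slc16a10 (26.6, the nearest other 38.4). In KO 2 they were Pfkfb4 (1.68 RPM, the nearest other 1.92), Cd52 (3.14, the nearest other 5.18) and Mpp3 (11.1, the nearest other 15). In KO 3 they were Akt1 (231.1 RPM, the nearest other 199.5), Fabp4 (349.1, the nearest other 289.5) and Wrnip1 (17.7, the nearest other 21.1), and in KO 4 Gm20735 (3.16, the nearest other 5.44) and St3gal5 (28.3, the nearest other 19.7).

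The number of genes that differed, 89, was larger than in every other split of the 8 libraries into 4 and 4. The highest other count was 4, and 1 of 35 splits, the real one, reached 89. That is the smallest share that 35 splits can give, and every other split mixes the genotypes, which adds their difference to the spread. The splits argue against chance assignment of the libraries for the gene count but cannot exclude it. For the number of lists, chance assignment stays open. There, 6 of the 35 splits, the real one included, gave 9 lists or more, and the highest other gave 15.

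The median gene lay 0.13 higher in KO on the deposited log2 scale, 0.08 without KO 3 and 0.06 without WT 3 and KO 3. A difference in depth, which moves genes with few reads, is argued against by the 6818 genes with a mean of 10 RPM or more, whose median log2 fold change was 0.12 (95% bootstrap interval over genes 0.11 to 0.13). That interval leaves out the spread between libraries: the jackknife SE over libraries was 0.056, the exact permutation p 0.0571, and the median ranged from 0.08 (without KO 3) to 0.15 (without KO 1) over single omissions. In a comparison added after the result was seen, genes with fewer reads shifted by only 0.013 more (jackknife SE over libraries 0.034), where depth as the whole cause would need about 0.13. A smaller share of reads on the 50 most abundant genes stays open: it was 34.3% ± 3.7 in KO and 38.4% ± 3.4 in WT (exact permutation p = 0.2, n = 4 each) and would move the other genes by 0.09. A change of total RNA per fibre with genotype was not tested. The scaling and the genotype cannot be told apart here, because a table scaled to a fixed total holds no outside reference.

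Endothelial markers lay higher in KO (camera adjusted p = 2.9e-04; adjusted p = 0.452 with an estimated correlation). Each group held 1 library with Xist, so an additive effect of sex would cancel between the groups by design. The endothelial score (the mean log2 value of the list) differed by 0.42 over all 8 libraries and by 0.51 among the 6 libraries without Xist. The difference therefore did not rest on the libraries with Xist. A lower share of fibre RNA would raise the markers of every other cell type alike. The endothelial score minus the mean of 5 other non-fibre scores was 0.43 higher in KO. Those 5 were the satellite cell, fibroblast, smooth muscle, tendon and Schwann cell lists. The tendon score, which differed by -0.46, enlarges this contrast. The macrophage and adipocyte scores, which differed by 0.36 and 0.15, were left out. The exact permutation p of 0.0857 (n = 4 per group) leaves a lower share of fibre RNA open. Whether the number of endothelial cells or their RNA content changed with genotype was not tested.

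KO 4 was the KO library nearest to WT in 47 of the 89 genes that differed, against 15, 21 and 6 for KO 1 to KO 3, and it held 2.73 times the mean residual Sdhc of the other KO libraries. More RNA of non-fibre cells, in which Sdhc was not deleted, could raise residual Sdhc. The 8 non-fibre lists lay a median of 0.36 higher in KO 4 on the log2 scale, below the 1.45 of the Sdhc ratio by more than their spread (SD 0.43), and ranged from -0.29 for endothelial cells to 0.92 for tendon, so that no list reached it. By this bound, set after its value was known, the values argue against non-fibre RNA as the whole cause of the residual Sdhc. Against an earlier bound, at 50% of the Sdhc ratio on the log2 scale, the same values had left that explanation open. A smaller part of non-fibre RNA in the residual Sdhc, or in the place of KO 4 nearest to WT, was not tested. An additive effect of sex could also set KO 4 apart. Over the 89 genes, deviations of KO 4 and of WT 1, the other library with Xist, from their groups correlated with r = 0.13 across genes, which are not independent, and this decides nothing. Less complete recombination in KO 4 was not tested.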

How the results depend on the processing

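The fits with an Xist term, on the 6 libraries without Xist, without WT 3 and KO 3, and with edgeR without TMM were chosen after the data were seen. In the alternatives in which each was tested, the direction of all 89 genes held and 9 of them stayed past the threshold throughout; 602 of 2023 single values fell short of it, and the cause was not tested. Against 89 genes (58 higher, 31 lower), no filter gave 59 (36 higher), where more genes were tested, and TMM factors gave 65 lower genes, quantile normalization 37 higher and 51 lower, edgeR 37 higher and 55 lower, and DESeq2 240 in all with 157 lower (649 adjusted p not given by the tool). Without a variance trend 14 genes were lower, and array weights gave 181 (123 and 58). The Xist term gave 235 (165 and 70), the 6 libraries without Xist 392 (247 and 145), and omission of WT 3 and KO 3 gave 9 (7 and 2). Leaving out 1 library gave 16 (without WT 3) to 263 (without KO 4) genes, 13 to 180 higher and 3 to 83 lower; the other values were 158 without WT 1, 26 without WT 2, 56 without WT 4, 29 without KO 1, 50 without KO 2 and 30 without KO 3. Pseudocounts of 0.5 (87 genes) and 5 (72 higher and 31 lower), a minimum of 5 RPM (69) and edgeR without TMM (80) stayed within 1.5 times the count.

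The number of lists, 9, was 0 with an estimated correlation and 5 (without KO 1) to 12 (without WT 1) when 1 library was left out. None of these 9 lists turned in direction. Exact p for Sdhc was 0.0571 in each omission of 1 library, the smallest that fewer libraries can give. Same-numbered libraries did not deviate together (residual correlations -0.01, 0.08, -0.12 and -0.09; 1 library correlated best with its own number). With the replicate block, 81 genes and 11 lists differed, and the sign-flip test of Sdhc gave 0.125, the smallest that 4 pairs allow.

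The sign of 7 genes that did not pass turned on the deposited log2 scale. With TMM factors Sdha stood at -0.01, Sdhb at -0.03, Sdhaf1 at -0.05 and Cs at -0.04; in both edgeR and DESeq2 they stood at -0.02, -0.05, -0.03 and -0.03, which removal of the median shift accounts for. Sdhaf1 was -0.07 with quantile normalization and without WT 3 and KO 3, and ranged from -0.05 to 0.19 over single omissions. Myh1 was 0.04 and Tnnt3 0 with quantile normalization. Fbxo32 was 0.02, 0.09 and 0.06 without WT 4, KO 1 and KO 4 (range -0.27 to 0.09) and 0.01 in edgeR without TMM. The cause of these values, apart from the median shift, was not tested. In simulated data 20.9% of 1.5-fold changes were recovered at this depth and replication, so that smaller changes were often not detectable. That share holds for genes with a mean of at least 5 RPM.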

Other observations

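The genes in this part lie outside the fixed lists or were picked after their values were seen, apart from those of the myostatin group that are in a list. Beside Mstn and Smad3, Wfikkn2, which encodes a secreted binding protein of myostatin, fell from 8.48 ± 0.991 to 4.38 ± 0.946 RPM (relative log2 fold change -0.95, limma adjusted p = 0.0475, n = 4 each). Stat5b, a transducer of growth hormone signals, fell from 113 ± 6.06 to 71.7 ± 9.41 RPM (-0.78, adjusted p = 0.0252), and the kinase Sgk1 from 333 ± 48.7 to 202.5 ± 23.7 RPM (-0.84, adjusted p = 0.0219). The aromatic amino acid transporter Slc16a10 fell from 66.1 ± 10.9 to 35.8 ± 6.18 RPM (-0.99, adjusted p = 0.02). All 4 KO libraries lay below all 4 WT libraries for each of these genes. Wfikkn2 lost its call in 12 of 23 alternatives, and Stat5b, Sgk1 and Slc16a10 in 7 each.

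Among genes that rose, Stbd1, which encodes a glycogen-binding protein, went from 93.2 ± 12.9 to 289.5 ± 135 RPM (relative log2 fold change 1.37, limma adjusted p = 0.0158), and Car1, a cytosolic carbonic anhydrase, from 5.12 ± 0.501 to 15.7 ± 2.87 RPM (1.31, adjusted p = 7.17e-04). The receptor Tnfrsf12a rose from 52 ± 9.64 to 105.3 ± 20.8 RPM and the NF-kappa-B subunit gene Nfkb2 from 27.7 ± 3.49 to 53.9 ± 8.79 RPM, both with an adjusted p of 0.0101, and each lost its call in 2 of 23 alternatives. Dnajb9, a chaperone of the endoplasmic reticulum, rose from 96.8 ± 14.7 to 158 ± 25.2 RPM (adjusted p = 0.0321). Stbd1 and Dnajb9 lost their calls in 3 and 6 of 23 alternatives. All 4 KO libraries lay above all 4 WT libraries for each of these genes.

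In the fit with a term for Xist, 97 genes passed for that term, and 3 of them, Mettl21c (-1.47 on the log2 scale, adjusted p = 0.00181), 1700001O22Rik (-1.76, adjusted p = 0.0175) and Lrtm2 (-0.97, adjusted p = 0.0284), were also among the 89, all lower both in KO and in the libraries with Xist. Tests of this term were chosen after the data were seen. Beside the Y-linked genes, Slc15a5, a member of a peptide transporter family, stood at 0.987 RPM in WT 1 and 0.961 RPM in KO 4 and between 22.2 and 44.2 RPM in the other 6 libraries.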
